A study of Mus musculus with 17 samples.

How the data were processed

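Gene expression was measured on 17 Affymetrix perfect-match arrays of mouse cells sorted by flow cytometry, in 6 groups. Wild-type spleen gave 3 pools of macrophages (CD11c-negative, CD11b-positive, M-CSF receptor-positive) and 3 pools of granulocytes (CD11c-negative, CD11b-positive, Ly6C-positive, M-CSF receptor-negative). Bone marrow gave myelo-dendritic progenitors (MDPs), sorted as lineage-negative, Sca1-negative, CD127-negative, CD117-positive and M-CSF receptor-positive cells. The MDPs came as 3 wild-type pools, 3 pools labelled IRF8 knockout, 3 pools that expressed the VENUS reporter and 2 pools without VENUS expression. Both VENUS groups carry the genotype label IRF8-deficient. The labels do not say whether that means the reporter allele itself, so the groups are named here by VENUS expression. Their titles read IRF8_PAC_MDP for the VENUS-positive and IRF8_neg_MDP for the VENUS-negative pools. Each pool of spleen cells, wild-type MDPs and knockout-labelled MDPs held cells of 5 mice, per the design text, and the number of mice per VENUS pool is not given in the sources used here. The mice were 6 to 10 weeks old. Per the labels' protocols, red blood cells were lysed, the stained cells were sorted into lysis buffer, total RNA was extracted on Qiagen columns and biotin-labelled cRNA was hybridised. Dendritic cell samples, which the design text also names, were not analysed here.

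The deposited values are log2 expression values, made by the authors with Affymetrix Expression Console and the RMA method, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set. Versions, and which arrays were normalized together, are not given in the sources used here. The values ran from 1.69 to 13.5 over 45037 probe sets, and the median of an array from 4.33 to 4.48, with no further centring. No columns were left unmapped to a sample, and 0 pairs of arrays held identical values. The platform annotation gave 1 gene symbol for 28898 probe sets, several for 551 and none for 15588, which are unnamed here. Entrez identifiers of 28689 probe sets were matched to a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only, and no symbol changed. Probe sets with 1 symbol covered 17097 genes, 7180 of them with several probe sets. The probe set with the highest mean over the 17 arrays stood for its gene, no gene was left out for low signal, and no coordinates are given because the array's genome build is not given in the sources used here.

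Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). One fit over all 17 arrays with a mean per group shared its estimate of the spread over the 6 groups (11 residual degrees of freedom, prior degrees of freedom 3.21). Adjusted p-values are limma's after the Benjamini-Hochberg method over the 17097 genes, and a gene was called at an adjusted p under 0.05. A difference in log2 units is the mean of the first group minus that of the second, a fold is 2 to that power (not given against levels near or under the lower quartile of the arrays, 3.18 to 3.42), SE is limma's standard error and SD the spread between pools. The p-values measure the spread between pools, and the number of arrays limits the precision. On simulated values for 17097 genes with 200 changed, the step recovered 51%, 60% and 64% of genes changed by 1 log2 unit for the knockout, VENUS and spleen comparisons, and 91%, 88% and 88% of those changed by 2 units. None was called with the wrong sign, and 3, 6 and 5 unchanged genes were called. The simulated values were independent normal draws with the same spread in all arrays for a gene. Unequal spreads between groups and correlated genes were not simulated, so these counts give no error rate for the real data.

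The genes named in the text follow a rule fixed before the data were examined. Irf8, Spi1 and the sort-gate genes come first. For the knockout, VENUS and spleen comparisons the rule takes the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap between groups, and for the other comparisons the 5 largest each way. Each gene list gives up to 4 called members with the largest difference, or the 2 with the smallest p. Predicted or RIKEN genes are named only among the 5 largest. Genes named outside it, in the overlap of the MDP comparisons, in the gene lists and in the levels per pool, were chosen after their values were seen.

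Lists of genes were also fixed before the data were examined, 24 in all: conventional and plasmacytoid dendritic cell genes, MHC class II presentation, monocyte and macrophage genes, primary granule genes, secondary and tertiary granule genes, eosinophil, basophil and mast cell genes, reported IRF8 targets, interferon-stimulated genes, myeloid transcription factors, stem and early progenitor genes, cell cycle, the BCL2 family, lysosome and phagocytosis, the genes of the mature and of the MDP sort gates, genes near Irf8, and markers of erythroid and megakaryocyte cells, B cells, T cells, NK cells, stroma and endothelium, stress during dissociation, and sex. Each list was compared with all other genes by limma's camera with its preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals. The p-values were adjusted over the 24 lists of a comparison, and list members were also counted after adjustment over the list alone. Some genes stand in several lists. Following the design text, a macrophage signature and a granulocyte signature were taken from the spleen arrays as genes called with a difference of at least 2 log2 units. Both signatures were tested in the MDP comparisons by camera. Overlaps of called genes were tested with one-sided Fisher's exact tests over all 17097 genes. These tests count genes as independent units, which they are not, so their p-values do not measure the spread between pools.

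The design text reads as if both spleen populations came from the same 3 pools, so these were treated as paired in an alternative with the pool as a block. In a fit of only macrophages and granulocytes 5108 genes were called without the block and 4500 with it. The correlation of the deviations of same-numbered spleen arrays from their group means was 0.0033, 0.0871 and 3.99e-04 for pools 1, 2 and 3. These values over all genes do not speak against pairing, because the sex-linked genes Xist and Eif2s3y ordered the pools alike in both populations. The counts of the Results come from the fit without the block unless stated. The alternatives were fits of only the compared groups, the pool number as a block in such fits, a trended robust prior, no dim genes, the mean of a gene's probe sets, cyclic loess, quantile normalization within the compared groups, array weights, a 2-fold minimum, other signature definitions, and each array left out in turn.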

Results

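Expression was compared among 6 groups of sorted mouse cells on 17 arrays. The groups were spleen macrophages (n = 3 pools), spleen granulocytes (n = 3), wild-type MDPs (n = 3), MDPs labelled IRF8 knockout (n = 3), VENUS-positive MDPs (n = 3) and VENUS-negative MDPs (n = 2). MDPs are bone marrow cells regarded as a common precursor of macrophages and dendritic cells, and IRF8 is a transcription factor of that lineage. Levels are the authors' RMA values on the log2 scale, given as mean ± SD over pools. Within groups the arrays correlated at r = 0.990 to 0.992 over probe sets for macrophages, 0.959 to 0.968 for granulocytes, 0.969 to 0.980 for wild-type MDPs, 0.972 to 0.976 for knockout-labelled MDPs, 0.960 to 0.971 for VENUS-positive MDPs and 0.967 for VENUS-negative MDPs. These correlations run across probe sets, which are not independent replicates.

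The targeted gene was examined first. Irf8 had a level of 10.34 ± 0.19 in wild-type MDPs and 10.31 ± 0.12 in the MDPs labelled knockout, a log2 difference of -0.03 (SE 0.42, adjusted p = 0.995). The other Irf8 probe set differed by -0.05. Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so they do not check the label, and the group is called knockout-labelled throughout. In VENUS-positive MDPs Irf8 stood at 10.88 ± 0.19 (n = 3) and in VENUS-negative MDPs at 5.87 ± 0.54 (n = 2), a fall of 32.2-fold (log2 difference -5.01, SE 0.46, adjusted p = 9.99e-06). The titles of both groups name IRF8, so the sort itself may have set this difference. Spleen macrophages had 9.17 ± 0.27 and granulocytes 6.37 ± 1.20. Spi1, which encodes the myeloid transcription factor PU.1, was at 7.58 ± 0.11 in knockout-labelled and 7.55 ± 0.30 in wild-type MDPs, and was lower in VENUS-negative than in VENUS-positive MDPs (log2 difference -1.47, adjusted p = 1.07e-04).

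The genes of the sort gates were read in the same way. Csf1r, the M-CSF receptor gene by whose protein all MDPs were sorted, had 7.56 ± 0.18 in wild-type, 7.35 ± 0.14 in knockout-labelled and 7.89 ± 0.23 in VENUS-positive MDPs, and 4.96 ± 0.19 in VENUS-negative MDPs. The VENUS-negative level was 7.62-fold below the VENUS-positive one (log2 difference -2.93, SE 0.30, adjusted p = 2.26e-05). Granulocytes, sorted as M-CSF receptor-negative, had 7.97 ± 0.73, above the mean of each MDP group, and macrophages 9.80 ± 0.12. Kit, which encodes CD117, was higher in VENUS-negative MDPs (log2 difference 1.32, adjusted p = 0.006), although without VENUS-negative pool 2 its adjusted p was 0.0583. In knockout-labelled minus wild-type MDPs, Kit differed by 0.66 (adjusted p = 0.329) and Csf1r by -0.21 (adjusted p = 0.953).

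**Figure D1:**
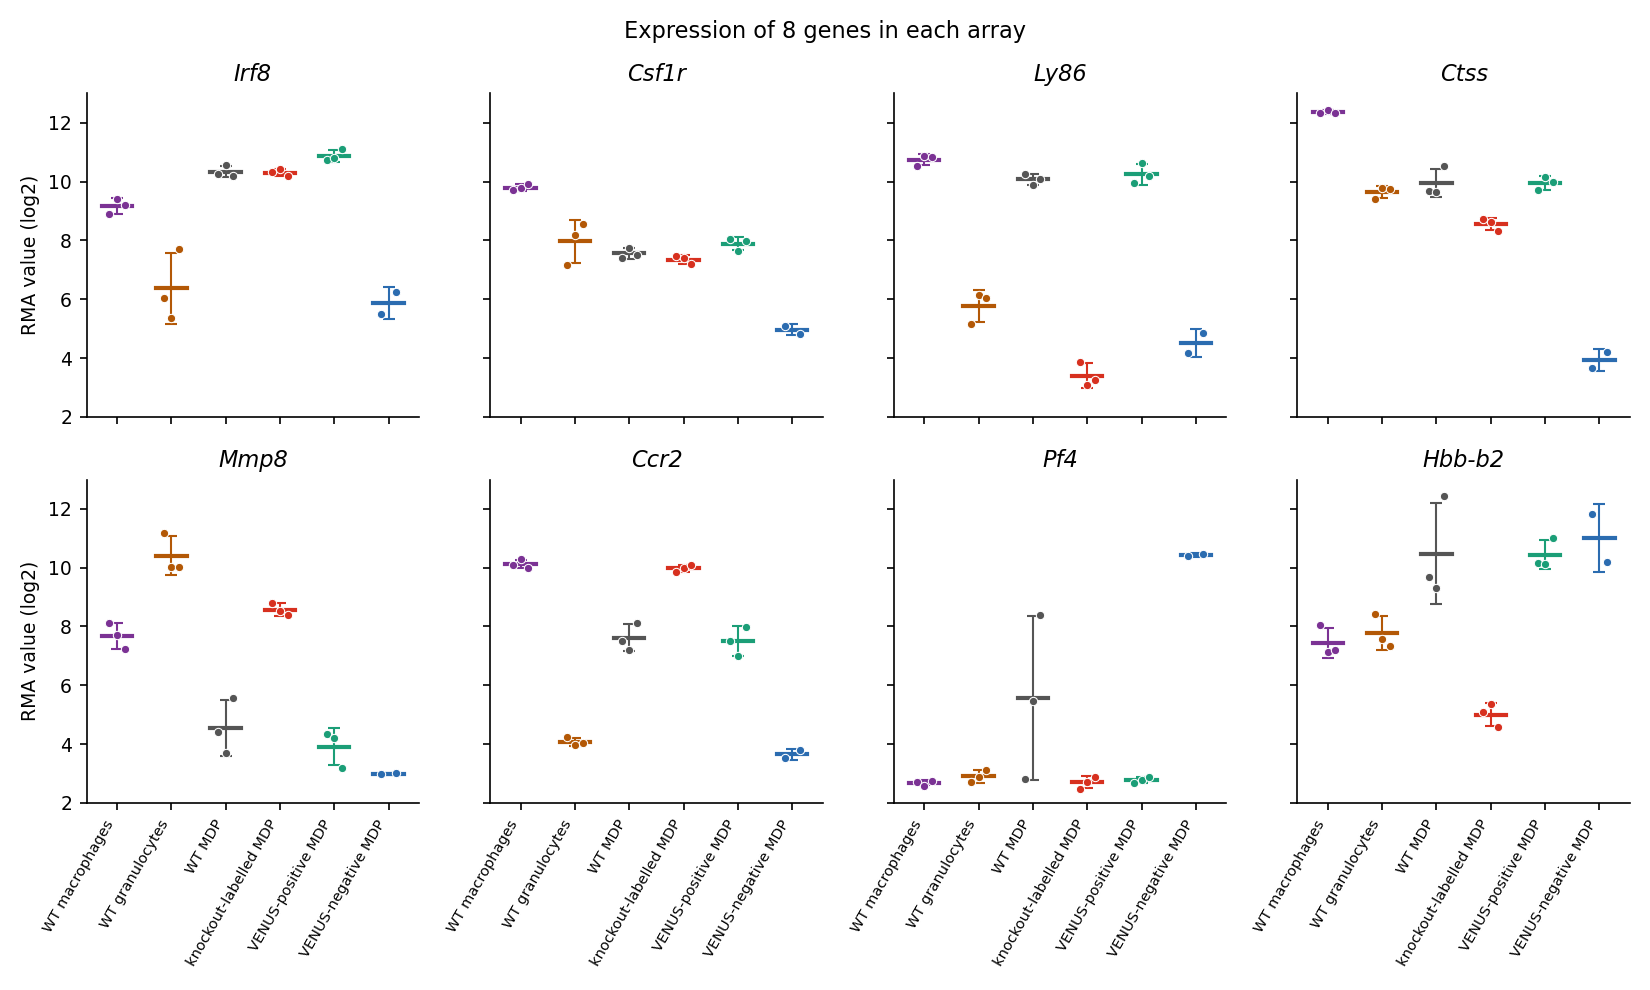
RMA values (log2) of 8 genes in each array, by group; points are pools, horizontal lines group means and bars the SD (n = 3 pools per group, 2 for VENUS-negative MDPs). Irf8 and Csf1r are low in VENUS-negative MDPs (means 5.87 and 4.96) but not in knockout-labelled MDPs (10.31 and 7.35), Ly86 is low in both (4.51 and 3.40), and Hbb-b2 is lowest in knockout-labelled MDPs (5.00).

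The first comparison set knockout-labelled MDPs against wild-type ones. Ly86, which encodes the Toll-like receptor cofactor MD-1, was lower in knockout-labelled MDPs (3.40 ± 0.42 against 10.08 ± 0.20, n = 3 and 3, log2 difference -6.69, SE 0.29, adjusted p = 1.62e-08). The cathepsin genes Ctsh (log2 difference -4.70, SE 0.29, adjusted p = 1.36e-06) and Ctse (-4.29) were lower as well, as were Tspan33 (-3.95), Lsp1 (-3.23) and Aff3 (-3.20). The largest rise was that of Mmp8, the neutrophil collagenase, at 8.58 ± 0.21 against 4.55 ± 0.94 (16.3-fold, log2 difference 4.03, SE 0.44, adjusted p = 3.22e-04). Tctex1d1 (3.81), 4933440M02Rik (3.61), Mrgpra2b (3.54), the chemokine receptor gene Ccr1 (3.43), Dmkn (3.34), Siglece (3.24), Gas7 (3.18), Slc36a2 (3.17) and Rtp4 (3.08) completed the 10 largest rises. Hbb-b2 (-5.47) and Hba-a1 (-4.76), which encode haemoglobin chains, and Car1 (-3.72) and Car2 (-3.12), which encode carbonic anhydrases, were among the 10 largest falls.

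In total 155 of 17097 genes were called, 78 higher and 77 lower, and 130 of them differed at least 2-fold. Without wild-type pool 1 the fit called 103 genes. A fit of only these 6 arrays called 46, and with the pool number as a block that fit called 2, Ly86 and Aff3. Among the genes named for this comparison, 11 lost their call in at least 1 fit without 1 array, with the highest adjusted p at 0.0671 for Hba-a1, 0.136 for Car2, 0.0823 for H2-DMa, 0.164 for Mgst1, 0.0813 for Trem3, 0.164 for Aif1, 0.0958 for Gbp2, 0.189 for Ddx58, 0.0808 for Cd34, 0.0817 for Ctsl and 0.0761 for Cd28.

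Wild-type pool 3 stood apart from the other wild-type pools in markers of mature cells. The mean level of the 24 secondary and tertiary granule genes was 4.74, 4.74 and 7.24 in wild-type pools 1, 2 and 3, against 6.25, 5.79 and 5.99 in the knockout-labelled pools. S100a8, a calprotectin gene of neutrophils, read 6.22, 3.62 and 11.9 in the wild-type pools. The means of the erythroid and megakaryocyte list were 5.32, 5.89 and 7.60, those of the monocyte and macrophage list 5.69, 5.71 and 6.76, those of MHC class II presentation 6.07, 5.99 and 6.99, and those of the NK-cell list 4.03, 4.08 and 5.33. Without this pool 159 genes were called, 93 higher and 66 lower, and 113 of the 155 kept their call.

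Of 13 MHC class II presentation genes, 0 were higher and 2 lower over all genes, and 5 were lower when adjusted over the list alone (median log2 difference -0.68, camera adjusted p = 6.09e-07, adjusted p = 0.155 with an estimated correlation). The called members were Ctss (-1.40), a cathepsin that processes the invariant chain, and H2-DMa (-1.31). Without wild-type pool 3 the median was -0.29 (adjusted p = 4.74e-04). Of 33 monocyte and macrophage genes, Ly86 and Ms4a4c (-2.02) fell and the chemokine receptor gene Ccr2 rose (2.36, adjusted p = 1.83e-04), with a median of -0.25 (adjusted p = 0.0096, and 0.615 with an estimated correlation) that became 0.00 without wild-type pool 3 (adjusted p = 0.988) and gave an adjusted p of 0.127 without knockout-labelled pool 3. Without wild-type pool 1, wild-type pool 2 or knockout-labelled pool 1 that median lay between -0.41 and -0.46. Of 18 reported IRF8 targets 2 were lower, Ctss and Aif1 (-2.30), with a median of -0.27 (adjusted p = 0.0071, and adjusted p = 0.311 with an estimated correlation). Without wild-type pool 3 its adjusted p was 0.129, and the median was -0.15 without knockout-labelled pool 2. Among 20 conventional dendritic cell genes, Dpp4 (-2.33) and Cd24a (-2.31) fell, but the list was not called (median -0.10, adjusted p = 0.0724) except without wild-type pool 2 (0.0487) or knockout-labelled pool 1 (0.0428), and 0 of 16 plasmacytoid dendritic cell genes were called (adjusted p = 0.598). Of 22 lysosome and phagocytosis genes, Ctsh and Ctss fell and Ctsl rose (1.42), and the list was not called (adjusted p = 0.0746) except without wild-type pool 1 (0.0431), wild-type pool 2 (0.0111) or knockout-labelled pool 1 (0.0428). With an estimated correlation no list kept its call in this comparison.

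Of 17 primary granule genes 1 was higher over all genes, Mgst1 (1.69, with another of its probe sets at -0.01), and 6 were higher and 2 lower when adjusted over the list alone (median 0.75, adjusted p = 5.60e-04, and adjusted p = 0.437 with an estimated correlation). Without wild-type pool 2 the median was 0.50 (adjusted p = 0.0199). Of 24 secondary and tertiary granule genes, Mmp8 and Trem3 (2.46) rose (median 0.16, adjusted p = 0.0191, and adjusted p = 0.615 with an estimated correlation). That median was -0.13 without wild-type pool 1 (adjusted p = 0.503), -0.07 without wild-type pool 2 (0.463), 0.84 without wild-type pool 3 (5.04e-12), and the adjusted p was 0.0836 without knockout-labelled pool 1.

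Of 18 erythroid and megakaryocyte marker genes 4 fell, namely Hbb-b2, Hba-a1, Car1 and Car2, and 10 were lower when adjusted over the list alone (median -1.29, camera adjusted p = 1.13e-13, adjusted p = 0.112 with an estimated correlation). Wild-type pool 3 had the highest levels of such markers among the wild-type pools. Pf4, a platelet chemokine gene, read 2.82, 5.46 and 8.39 in wild-type pools 1, 2 and 3, and Klf1, an erythroid transcription factor gene, 4.61, 4.83 and 7.67. Without that pool the list's median was -0.81 (adjusted p = 3.89e-10). Of 15 eosinophil, basophil and mast cell genes 0 were called (median -0.55, adjusted p = 0.0071), and the median was -0.01 without wild-type pool 3 (adjusted p = 0.988), where Cpa3, a mast cell protease gene, read 6.31 against 2.87 and 2.98 in wild-type pools 1 and 2. With an estimated correlation the adjusted p of that list was 0.615.

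Of 28 interferon-stimulated genes 3 rose, among them Rtp4, Gbp2 (1.49) and Ddx58 (1.45), and 2 fell, among them Trim30a (-1.34), with no shift of the list (median 0.14, adjusted p = 0.715). Of 24 stem and early progenitor genes Cd34 fell (-1.25; median -0.24, adjusted p = 0.0089, and 0.112 with an estimated correlation), and of 43 myeloid transcription factor genes Bach2 fell (-1.34; adjusted p = 0.755). The 35 cell cycle genes had a median of -0.15 with 0 called (adjusted p = 0.0468, and 0.800 with an estimated correlation), and that adjusted p lay between 0.0568 and 0.303 without wild-type pool 1, wild-type pool 3, knockout-labelled pool 1 or knockout-labelled pool 2, with medians from -0.08 to -0.29 over all such fits. The 15 stress genes had a median of 0.37 with 0 called (adjusted p = 0.044, and 0.615 with an estimated correlation), which was 0.06 without knockout-labelled pool 1 (adjusted p = 0.585), 0.68 without knockout-labelled pool 3 (6.44e-05), 0.25 without wild-type pool 2 (0.32) and 0.27 without knockout-labelled pool 2 (0.179). Vpreb1, a pre-B-cell receptor gene, rose (2.46) among 12 B-cell genes (adjusted p = 0.598), and Cd28 rose (1.37) among 11 T-cell genes (adjusted p = 0.402). The 14 NK-cell genes had a median of -0.19 with 0 called and a list adjusted p of 0.050, only just under the threshold (adjusted p = 0.615 with an estimated correlation). That median was 0.06 without wild-type pool 3 (adjusted p = 0.988), -0.13 without knockout-labelled pool 1 (0.159) and -0.22 without knockout-labelled pool 2 (0.0882), and -0.40 and -0.35 without wild-type pools 1 and 2 (0.00371 and 0.00971). No gene was called among the 14 BCL2 family genes (0.920), the 29 genes near Irf8 (0.755), the 12 stroma and endothelium genes (0.920), the 4 sex-linked genes (0.440), the 4 genes of the mature gate (0.715) and the 2 of the MDP gate (0.495).

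The next comparison set MDPs without VENUS against those with it. Pf4 stood at 10.42 ± 0.06 in VENUS-negative against 2.77 ± 0.10 in VENUS-positive MDPs (n = 2 and 3), the latter under the lower quartile of all probe sets (log2 difference 7.65, SE 0.97, adjusted p = 1.54e-04). Car1 (6.08), Mfsd2b (6.04), Ctla2a (5.56), Ces2g (5.55), the mast cell genes Cpa3 (5.52) and Ms4a2 (5.52), the thrombin receptor gene F2r (5.47), Ermap (5.32) and Cd55 (5.07) followed. Ctss fell from 9.95 ± 0.23 to 3.93 ± 0.36, the latter under the median of all probe sets (log2 difference -6.02, SE 0.25, adjusted p = 3.16e-09). Mpeg1, which encodes the macrophage pore-forming protein perforin-2, fell by a log2 difference of -5.98, F13a1, a coagulation factor gene of monocytes, by -5.95, and Ly86 by -5.75. Irf8, Met (-4.91), Ifi209 (-4.76), Ms4a6c (-4.59), the monocyte transcription factor gene Klf4 (-4.50) and Ctsh (-4.38) completed the 10 largest falls. In total 1003 genes were called, 487 higher and 516 lower, and 807 of them differed at least 2-fold. A fit of only these 5 arrays called 459 genes, and 98 with a block for the pool number, in which VENUS-positive pool 3 has no partner. Leaving out 1 array left 732 to 948 called.

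Of 18 erythroid and megakaryocyte genes 9 rose and 0 fell, and 12 rose when adjusted over the list alone (median 1.92, camera adjusted p = 1.15e-14, adjusted p = 0.0913 with an estimated correlation). Pf4, Car1, Ermap and Car2 (4.81) rose most, and without VENUS-negative pool 2 the median was 2.90 (adjusted p = 2.25e-17). Of 15 eosinophil, basophil and mast cell genes 6 rose and 0 fell, led by Cpa3, Ms4a2, the histidine decarboxylase gene Hdc (3.03) and Siglecf (2.91; median 1.95, adjusted p = 2.67e-08, and 0.136 with an estimated correlation). Of 24 stem and early progenitor genes 6 rose and 3 fell (median 0.46, adjusted p = 0.0217, and 0.0941 with an estimated correlation). Angpt1 (4.04), Meis1 (2.18) and Adgrg1 (1.79) rose and Cd34 fell (-1.56). That median was 0.23 without VENUS-positive pool 1 (adjusted p = 0.0534), 0.26 without VENUS-positive pool 3 (0.0457) and 0.04 without VENUS-negative pool 2 (0.326).

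Of 33 monocyte and macrophage genes 11 fell and 1 rose (median -0.27, camera adjusted p = 5.24e-08, adjusted p = 0.154 with an estimated correlation). Of 22 lysosome and phagocytosis genes 8 fell and 1 rose, with Psap at -2.86 and Cd68 at -1.70 besides the cathepsin genes (median -0.65, adjusted p = 4.25e-07, and 0.0941 with an estimated correlation). Of 20 conventional dendritic cell genes 5 fell and 0 rose, led by the cytokine receptor gene Flt3 (-3.47), Btla (-3.33), Kmo (-2.61) and Sirpa (-2.21). That list had a median of -0.43 (adjusted p = 9.86e-05, and 0.136 with an estimated correlation), and of -0.27 without VENUS-negative pool 1 (3.83e-04). Of 13 MHC class II presentation genes 4 fell, among them Ctss, H2-DMb1 (-1.98) and H2-DMb2 (-1.87), and H2-Ob rose (1.46; adjusted p = 0.0719 without VENUS-negative pool 2). Their median was -0.48 (adjusted p = 0.0012, and 0.231 with an estimated correlation), and ranged down to -0.87 with 1 array left out (VENUS-positive pool 2). Of 18 reported IRF8 targets 4 fell, namely Ctss, Klf4, Aif1 (-4.30) and the cystatin gene Cst3 (-1.32). That list had a median of -0.15 (adjusted p = 0.002, and 0.136 with an estimated correlation), of -0.23 without VENUS-negative pool 1 and of -0.04 without VENUS-negative pool 2. Of 43 myeloid transcription factor genes 10 fell and 3 rose, with Gata1, of the erythroid lineage, at 4.53 and Nfil3 at -2.73 (median -0.27, adjusted p = 0.0145, and 0.154 with an estimated correlation). That adjusted p was 0.0539 without VENUS-positive pool 3 and 0.0883 without VENUS-negative pool 1.

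The genes of the mature sort gate formed the only list that kept its call in the VENUS comparison with an estimated correlation. Of its 4 genes Csf1r, Ly6c1 (-2.45) and the CD11c gene Itgax (-1.46) fell (median -1.95, adjusted p = 7.06e-05, and 0.0277 with an estimated correlation). The call of Itgax was lost without either VENUS-negative pool (highest adjusted p = 0.115). Of 14 BCL2 family genes 3 fell, Pmaip1 (-2.52), Bcl2 (-1.41) and Bid (-1.38), and the list was not called (adjusted p = 0.195). Of 28 interferon-stimulated genes 4 rose and 4 fell (adjusted p = 0.958), among them Ddx58 (1.97) and Ifi27l2a (-2.73). Of 17 primary granule genes Gfi1b (3.94), a gene also used in megakaryocytes and erythroid cells, and Nkg7 (2.19) rose and Mgst1 fell (-1.60; adjusted p = 0.958), and of 24 secondary and tertiary granule genes Csf3r fell (-1.20; adjusted p = 0.786). The 35 cell cycle genes had a median of -0.33 with 0 called (adjusted p = 0.034, and 0.948 with an estimated correlation), and the list's adjusted p was 0.744 without VENUS-negative pool 2, 0.216 without VENUS-positive pool 3 and 0.0528 without VENUS-positive pool 2. The other lists were not called, at adjusted p = 0.854 for plasmacytoid dendritic cells, where Tcf4 (-1.26) and Atp1b1 (-1.57) fell, 0.973 for B cells, 0.958 for T cells, where Lat rose (2.74), 0.973 for NK cells, where Gzmb rose (2.47), 0.973 for stroma and endothelium, 0.521 for stress, 0.772 for the MDP gate and 0.958 for genes near Irf8. With 1 array left out, the adjusted p rose as high as 0.096 for Nkg7 and Pmaip1, 0.149 for Mgst1, 0.294 for Csf3r (difference -0.76), 0.127 for Bcl2, 0.095 for Bid and 0.104 for Cd68, and the difference of Gzmb was 1.33 without VENUS-negative pool 2.

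The sex-linked list showed that the pools were not matched for sex. Xist, transcribed from the inactive X chromosome of females, read 5.44, 4.86 and 11.6 in VENUS-positive pools 1, 2 and 3 and 5.37 and 5.54 in the VENUS-negative pools, and 10.3 to 11.9 in the wild-type and knockout-labelled MDP pools. The Y-linked gene Eif2s3y read 5.0, 5.1 and 7.1 in wild-type pools 1, 2 and 3 and 4.9, 2.5 and 6.7 in the knockout-labelled ones. High Xist therefore does not show that these pools were all female or matched. In spleen pools 1, 2 and 3 Xist read 5.0, 9.5 and 10.4 in macrophages and 5.3, 8.7 and 9.3 in granulocytes. The list was not called in the VENUS comparison (adjusted p = 0.392).

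**Figure D2:**
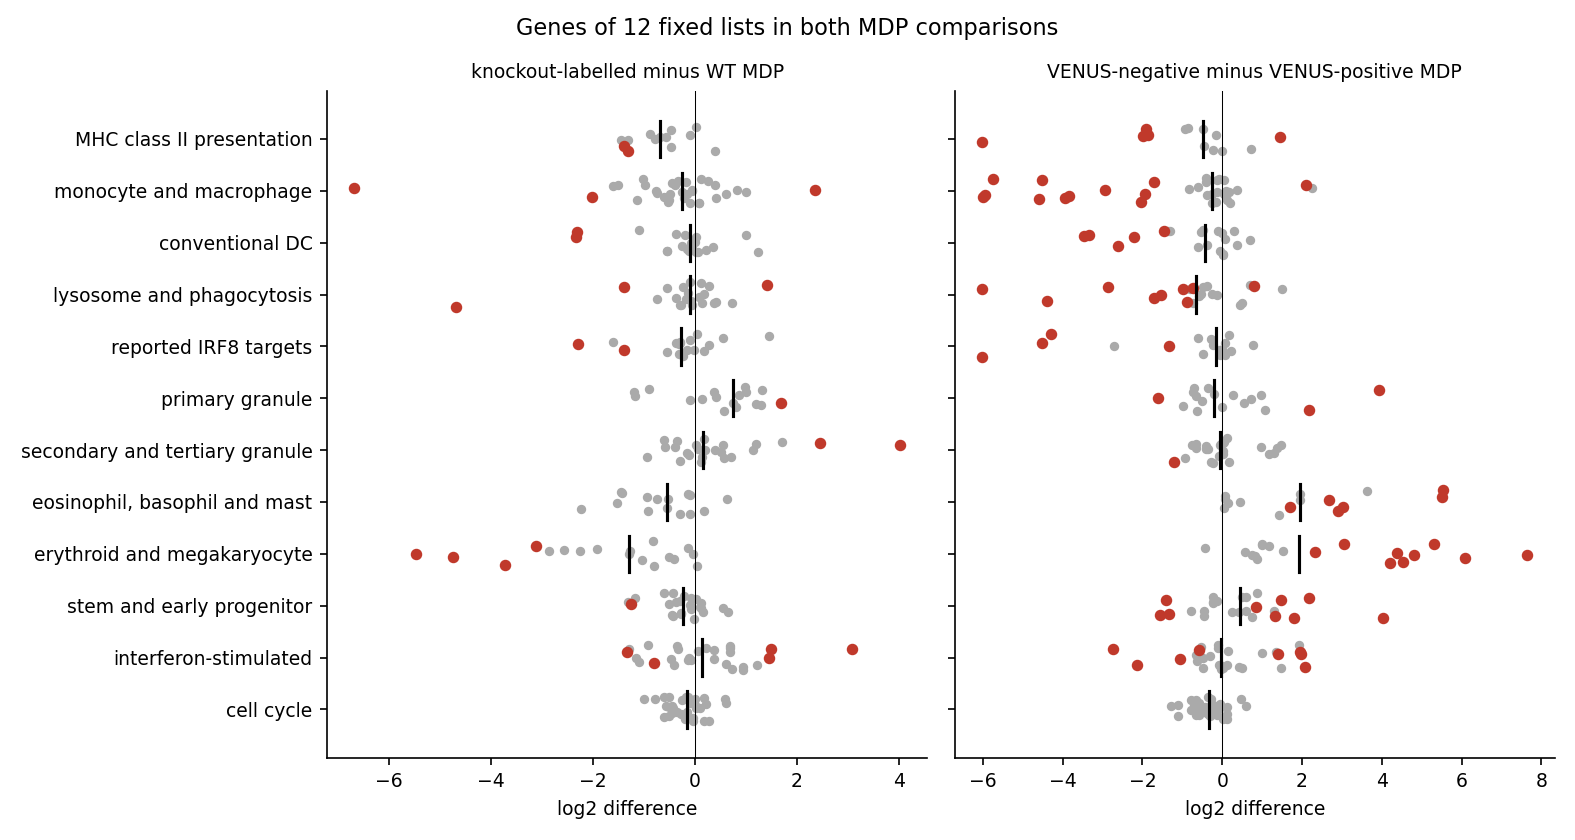
Log2 differences of the members of 12 fixed gene lists in the knockout comparison (left) and the VENUS comparison (right); each point is a gene, red for an adjusted p under 0.05 over all genes, and black lines mark list medians. In the knockout comparison the erythroid and megakaryocyte list has its median at -1.29, and in the VENUS comparison at 1.92.

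The MDP comparisons were then set side by side. They share no arrays, though both use the variance estimate of the same fit. Genes lower in both knockout-labelled and VENUS-negative MDPs numbered 37, where independent lists give 2.32 (one-sided Fisher's exact p = 6.64e-36). They included Ly86, Ctsh, Lsp1, Aif1, Ctss, Bach2 and Cd34. Another 8 genes were higher in both against 2.22 (Fisher's exact p = 0.0017), among them the interferon-stimulated genes Rtp4, Gbp2 and Ddx58, though Rtp4 was not called in the VENUS comparison without VENUS-positive pool 2 or VENUS-negative pool 2 (highest adjusted p = 0.254). Higher in knockout-labelled and lower in VENUS-negative MDPs were 10 genes against 2.35 (Fisher's exact p = 1.15e-04), among them Ccr2. Lower in knockout-labelled and higher in VENUS-negative MDPs were 9 genes against 2.19 (Fisher's exact p = 3.32e-04), among them Car1 and Car2. When each comparison was fitted on its own arrays, 6 genes were lower in both (Ctsh, Fbxw4, Haao, Ly86, Thbd and Tmem229b) against 0.371. Across all 17097 genes, which are not independent replicates, the differences correlated at Pearson r = 0.023 (jackknife SE over the 11 MDP arrays 0.0729) and Spearman rho = 0.088.

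**Figure D3:**
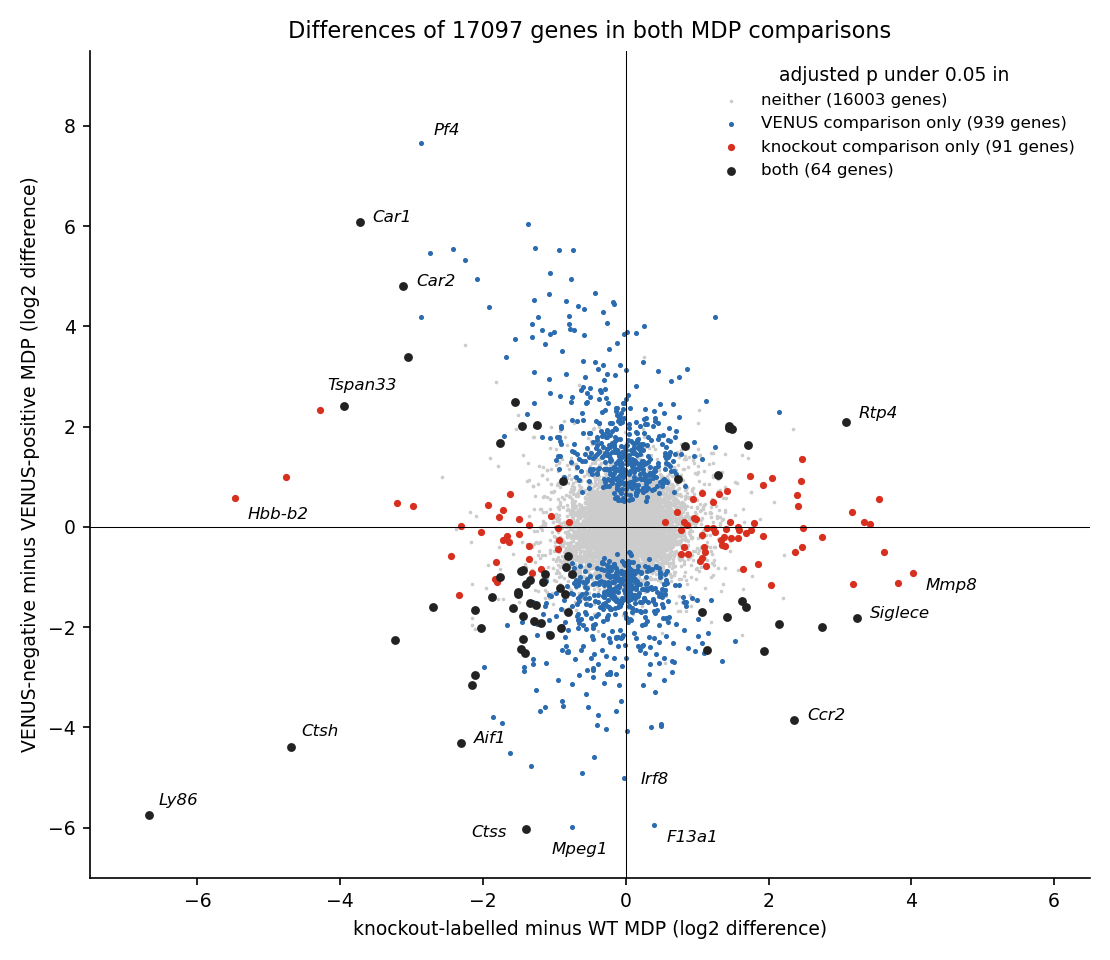
Log2 difference of each of 17097 genes between knockout-labelled and wild-type MDPs (x axis) and between VENUS-negative and VENUS-positive MDPs (y axis). Colours mark genes at an adjusted p under 0.05 in both comparisons (black, 64 genes), in the knockout comparison (red, 91), in the VENUS comparison (blue, 939) or in neither (grey, 16003). Ly86 and Ctsh lie far down in both, and Pf4 and Ccr2 in opposite directions, Pf4 being called in the VENUS comparison only.

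A test of the difference between these differences called 615 genes, 318 with a more positive knockout difference and 297 with a more negative one. F13a1 (6.34), Ccr2 (6.21), Mpeg1 (5.23), Siglece (5.05) and Irf8 (4.98) had the largest positive values, on the log2 scale. Pf4 (-10.52), Car1 (-9.80), F2r (-8.21), Ces2g (-7.97) and Car2 (-7.93) had the largest negative ones. Pf4 read 2.82, 5.46 and 8.39 in wild-type pools 1, 2 and 3, and was not called in the knockout comparison. Of the 18 erythroid and megakaryocyte genes 11 had more negative knockout differences and 0 more positive ones (median -4.44, camera adjusted p = 6.00e-25, adjusted p = 0.016 with an estimated correlation). This list test was not repeated without wild-type pool 3, which had the highest levels of such markers among the wild-type pools.

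Mature spleen populations were compared to derive lineage signatures. Macrophages and granulocytes differed in 5337 genes, 3142 higher and 2195 lower in macrophages, of which 3202 differed at least 2-fold (2245 higher, 957 lower). The split by direction depended on the processing, with 2443 higher and 2250 lower after cyclic loess and 2979 and 1078 without dim genes. A fit of only these 6 arrays called 5108 genes, and 4500 with the pool as a block. F13a1 was 89.2-fold higher in macrophages (10.74 ± 0.27 against 4.26 ± 0.06, n = 3 and 3, log2 difference 6.48, SE 0.16, adjusted p = 3.65e-12), followed by Ms4a6d (6.20, with another of its probe sets at -0.02), Ccr2 (6.05), Ms4a6b (5.91), Ms4a6c (5.66), the fibronectin gene Fn1 (5.55), the Fc receptor gene Fcgr1 (5.45), S100a4 (5.41), Nupr1 (5.40) and Ptpro (5.40). Stfa2l1, a stefin gene, was at 10.45 ± 0.11 in granulocytes and 2.41 ± 0.13 in macrophages, the latter under the lower quartile (log2 difference -8.04, SE 0.12, adjusted p = 3.59e-15). Il1f9 (-7.20), the gelatinase gene Mmp9 (-6.98), Mgam (-6.61), the neutrophil granule genes Lcn2 (-6.61) and Ltf (-6.49), Chil1 (-6.59), Hdc (-6.58), H2-Q10 (-6.52) and the chemokine receptor gene Cxcr2 (-6.49) were also higher in granulocytes.

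All 13 MHC class II presentation genes were higher in macrophages (median 3.08, camera adjusted p = 8.52e-11, adjusted p = 0.116 with an estimated correlation), led by H2-DMa (4.80) and Ifi30 (4.32). Of 33 monocyte and macrophage genes 21 were higher there and 2 lower (adjusted p = 1.26e-10, and 0.173 with an estimated correlation), and of 22 lysosome genes 15 higher and 1 lower (4.07e-07, and 0.116). Of 18 reported IRF8 targets 7 were higher and 0 lower (0.005, and 0.194), led by Klf4 (5.04) and Aif1 (4.76), and of 20 conventional dendritic cell genes 9 were higher and 1 lower (5.08e-04, and 0.179). Of 24 secondary and tertiary granule genes 20 were higher in granulocytes and 0 in macrophages (median -3.54, adjusted p = 5.81e-15, and 0.116 with an estimated correlation). Of 14 NK-cell genes 12 were higher there (median -2.34, adjusted p = 1.45e-06, and 0.179 with an estimated correlation), with Gzma, a cytotoxic granule protease gene, at 10.88 ± 0.63 against 5.18 ± 0.82 (log2 difference -5.69), Klra8 (-4.81), Ccl5 (-3.88) and Tbx21 (-3.56). Of 15 eosinophil, basophil and mast cell genes 7 were higher there (adjusted p = 0.0047, and 0.455 with an estimated correlation), among them Siglecf (-4.47) and the eotaxin receptor gene Ccr3 (-2.35). Of 15 stress genes 10 were higher in granulocytes and 3 lower (median -1.05, adjusted p = 0.0123, and 0.455 with an estimated correlation). Of 11 T-cell genes 3 were higher there (median -0.39, adjusted p = 0.035, and 0.289 with an estimated correlation), with an adjusted p of 0.0628 without granulocyte pool 2 and 0.055 without granulocyte pool 3. The cell cycle list was lower in macrophages (median -0.90, 12 of 35 genes lower and 1 higher, adjusted p = 0.0018, and 0.599 with an estimated correlation), but not without granulocyte pool 1 (median -0.42, adjusted p = 0.168).

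The lineage signatures held 646 macrophage and 333 granulocyte genes. In knockout-labelled minus wild-type MDPs the macrophage signature had a median of -0.07 with 6 genes higher and 21 lower (camera p = 0.004, adjusted over 4 tests 0.0079, and p = 0.254 with an estimated correlation), but the median was 0.03 without wild-type pool 3 (p = 0.401). For the granulocyte signature the median was 0.01 (camera adjusted p = 0.374). Without wild-type pool 3 it was 0.09, past the unadjusted threshold of 0.05. Of its genes 8 were higher and 3 lower. Of the 77 genes lower in knockout-labelled MDPs 21 belonged to the macrophage signature where 2.91 are given by independent lists (one-sided Fisher's exact p = 5.29e-13), with Ly86, Tspan33, Dpp4 and Aif1 among them. The Fisher p-values here treat genes as independent, and whether this overlap holds without wild-type pool 3 was not tested. Of the 78 higher genes 8 belonged to the granulocyte signature against 1.52 (Fisher's exact p = 1.36e-04), namely Mmp8, Mrgpra2b, Ccr1, Siglece, Trem3, Cd33, Pde2a and Hk3. The last 4 lost their call in at least 3 fits without 1 array each (highest adjusted p = 0.188, for Pde2a). In VENUS-negative minus VENUS-positive MDPs the macrophage signature had a median of -0.15 with 14 genes higher and 93 lower (camera p = 2.62e-06, adjusted 1.05e-05, and p = 0.0752 with an estimated correlation). The granulocyte signature had a median of 0.06 with 30 genes higher and 14 lower (camera p = 0.0375, adjusted 0.050, and p = 0.378 with an estimated correlation). Its unadjusted p did not stay under 0.05 without VENUS-positive pool 1, VENUS-positive pool 2 or VENUS-negative pool 2, with a median of -0.01 without VENUS-positive pool 2. Of the 516 genes lower in VENUS-negative MDPs 93 lay in the macrophage signature against 19.5 (Fisher's exact p = 1.18e-37), and of the 487 higher genes 30 lay in the granulocyte signature against 9.49 (Fisher's exact p = 2.82e-08), among them Hdc, Siglecf and Gzmb.

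Against wild-type MDPs, macrophages differed in 4038 genes (1949 higher, 2089 lower) and granulocytes in 7720 (3768 higher, 3952 lower). Of the granulocyte genes 4776 differed at least 2-fold, 1672 higher and 3104 lower. The invariant chain gene Cd74 (97.0-fold), Slfn1 (6.52), the kinase gene Fgr (6.23), Klra2 (6.23) and Slfn5 (5.94) rose most in macrophages, and Ctsg (-7.31), Cd34 (-6.71), the myeloperoxidase gene Mpo (-6.38), Myb (-6.08) and the neutrophil elastase gene Elane (-5.85) fell most. In granulocytes Stfa2l1 (7.96), the interleukin-1 beta gene Il1b (7.88), Slfn1 (7.77), Slfn4 (7.59) and Il1r2 (7.56) rose most, and Cnn3 (-6.57), Abhd14a (-6.44), Ctsg (-6.33), Cd34 (-6.33) and F13a1 (-6.23) fell most. Of 28 interferon-stimulated genes 26 were higher in macrophages and 0 lower (median 2.65, camera adjusted p = 5.38e-24, adjusted p = 0.0133 with an estimated correlation). Of 24 stem and early progenitor genes 14 were lower in macrophages and 0 higher (adjusted p = 1.11e-07, and 0.0019 with an estimated correlation). All 24 secondary and tertiary granule genes were higher in granulocytes (median 5.36, adjusted p = 3.04e-14, and 0.198 with an estimated correlation). Of 35 cell cycle genes 33 were lower in macrophages (adjusted p = 5.38e-24, and 0.0628 with an estimated correlation) and 29 in granulocytes (adjusted p = 1.91e-09, and 0.535 with an estimated correlation).

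VENUS-positive and wild-type MDPs were compared to see whether reporter MDPs differ from wild-type ones. Limma called 0 genes, with the smallest adjusted p at 0.232, while 1027 genes (6.01%) had an unadjusted p under 0.05. The fits without 1 array called 0 to 4 genes, the 4 without wild-type pool 1. Camera called shifts of the primary granule list (median -0.66, adjusted p = 1.51e-07), the stress list (-0.58, 1.51e-07), the erythroid and megakaryocyte list (-0.63, 1.45e-06), the secondary and tertiary granule list (-0.53, 5.77e-05), the eosinophil, basophil and mast cell list (-0.76, 1.66e-04) and the monocyte and macrophage list (-0.26, 0.0026). None of these held with an estimated correlation (lowest adjusted p = 0.249), and the mean of each was higher in wild-type pool 3 than in the other 2 wild-type pools. VENUS-negative and knockout-labelled MDPs differed in 1102 genes, 509 higher and 593 lower in VENUS-negative MDPs. Pf4 (7.73), F2r (7.22), Car1 (7.18), Car2 (6.26) and Mfsd2b (6.09) rose most, and F13a1 (-6.44), Ccr2 (-6.33), Mmp8 (-5.59), Tctex1d1 (-5.04) and Gas7 (-4.98) fell most. Of 18 erythroid and megakaryocyte genes 11 were higher in VENUS-negative MDPs and 0 lower (median 3.85, camera adjusted p = 8.70e-21, adjusted p = 0.0202 with an estimated correlation).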

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

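The test of the difference between both MDP effects was planned, and the counts over probe sets without a gene name were chosen after the data had been examined. The difference between the knockout effect and the VENUS effect passed the test for 615 genes. Of these, 19 were called in both comparisons with opposite signs, among them Car1, Car2 and Ccr2, and 4 with the same sign. Another 465 were called in the VENUS comparison alone, 50 in the knockout comparison alone and 77 in neither.

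Probe sets without a gene name, or with several, were left out of the comparisons of genes and tested apart, 16139 in all. In the knockout comparison 53 of them passed the same test, 23 higher and 30 lower, with log2 differences up to 3.26 (adjusted p = 0.0143) and down to -5.17 (adjusted p = 0.009). In the VENUS comparison 415 passed it, 232 higher and 183 lower, with differences up to 5.98 (adjusted p = 5.81e-06) and down to -5.10 (adjusted p = 1.39e-06).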

How the results depend on the processing

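Added after the data had been examined were the alternatives for the overlap of both MDP comparisons and the signatures without genes of the NK-cell, B-cell, T-cell and eosinophil, basophil and mast cell lists. The signs of the 155 knockout and 1003 VENUS differences held wherever their genes were tested. That is a weak check, since for 155 and 1002 of them the arrays did not overlap between groups. Leaving out an array could not turn the sign of those. In fits of only the groups compared, 46 genes were called for the knockout comparison, 459 for VENUS-negative minus VENUS-positive MDPs and 649 for VENUS-negative minus knockout-labelled MDPs. Such fits have fewer arrays to estimate the spread and do not share it with the other groups. Quantile normalization within the compared groups, fitted on the same arrays, gave 61, 444 and 620. Adding the pool number as a block to the fits of only the groups compared left 2, 98 and 110, and 365 instead of 430 for the difference between both MDP effects. VENUS-negative MDPs have no pool 3, so pool 3 of the other group adds nothing to the difference in the blocks that gave 98 and 110. Deviations of same-numbered MDP arrays correlated at -0.0916 to 0.0946. Macrophages minus wild-type MDPs went the other way, from 4038 genes to 5250 in the fit of only these groups and 5592 with array weights. A fit with fewer arrays therefore did not always call fewer genes. Whether fewer arrays gave the falls in the MDP comparisons was not tested. Array weights raised the knockout count to 259. The cause was not tested. A minimum of 1 log2 unit left 3202 genes between macrophages and granulocytes and 4776 between granulocytes and wild-type MDPs. With each array left out in turn, the counts ran from 103 to 159 for the knockout comparison and from 0 to 4 for VENUS-positive minus wild-type MDPs.

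The macrophage signature in the knockout comparison kept its median of -0.0691 with an estimated correlation (p = 0.254), had -0.0264 with signature genes differing by at least 1 log2 unit (p = 0.105), and ran from -0.121 to 0.0260 with each array left out. The granulocyte signature there ran from -0.0119 to 0.0949, and it passed the unadjusted threshold without dim genes (0.0697) and without wild-type pool 3 (0.0949). In the VENUS comparison the estimated correlation left the macrophage signature at -0.149 (p = 0.0752) and the granulocyte signature at 0.0583 (p = 0.378). The latter no longer passed with genes differing by at least 1 log2 unit (0.0225), after cyclic loess (0.0105) or without the genes of the other cell types (0.0528), and ran from -0.0113 to 0.0544 with each array left out. The monocyte and macrophage list in the knockout comparison ran from -0.462 to 0.00362, its sign turning without wild-type pool 3. The correlation of both effects was 0.0969 over the genes called in the knockout comparison, and 6 genes were lower in both when each comparison was fitted on its own arrays. For these, too, the cause was not tested. Of 584 values of named genes, called or not, 492 kept that status in fits of only the groups compared (83 lost a call and 9 gained one), 441 with the block (140 and 3) and 489 with quantile normalization within groups (85 and 10), and none reversed. Signal over background could not be set apart, since the deposited values are already background-corrected.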

Other observations

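The levels below, and all tests of explanations, were chosen after the results were seen, while the counts over other splits of the arrays were planned. Mmp8 was at 8.58 ± 0.21 in knockout-labelled MDPs, between 4.55 ± 0.94 in wild-type MDPs and 10.41 ± 0.66 in spleen granulocytes (n = 3 pools each), and at 2.99 ± 0.03 in VENUS-negative MDPs (n = 2). Siglece, a sialic acid receptor gene, and Trem3 followed that order, with 8.56 ± 0.38 and 8.97 ± 0.29 in knockout-labelled MDPs, 5.31 ± 0.82 and 6.51 ± 0.96 in wild-type MDPs and 10.78 ± 0.08 and 9.92 ± 0.60 in granulocytes. Macrophage pools 1, 2 and 3 also lay above the wild-type MDP means, at 8.1, 7.7 and 7.2 for Mmp8 and 7.3, 7.5 and 7.0 for Trem3. A level above wild-type MDPs in these 2 genes is thus not particular to granulocytes. Ccr2 stood at 9.98 ± 0.11 in knockout-labelled MDPs and at 10.12 ± 0.15 in macrophages, against 7.62 ± 0.47 in wild-type MDPs, by the probe set used, while its 3 other probe sets put each knockout-labelled pool below each macrophage pool. F13a1 was at a similar level in wild-type MDPs (10.49 ± 0.07), knockout-labelled MDPs (10.88 ± 0.08) and macrophages (10.74 ± 0.27), and at 4.45 ± 0.26 in VENUS-negative MDPs, near the 4.26 ± 0.06 of granulocytes.

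Of the primary granule genes, 14 of 17 did not pass the test between VENUS-negative and VENUS-positive MDPs. In that list 2 genes were called higher and 1 lower, against 1003 called among all 17097 genes. With 2 VENUS-negative pools, not passing does not show an equal level. Among those 14, Ctsg was at 11.16 ± 0.30 and 11.52 ± 0.02 (log2 difference -0.36, adjusted p = 0.828), and Elane at 10.06 ± 0.28 and 9.33 ± 0.31 (0.73, adjusted p = 0.640). Of transcription factor genes, Klf1 (log2 difference 4.39, adjusted p = 7.71e-04), Gata2 (2.67, adjusted p = 4.27e-06) and Stat5a (1.23, adjusted p = 0.00165) rose, and Satb1 (-1.80, adjusted p = 1.18e-04) fell. Epor, the erythropoietin receptor gene, stood at 8.38 ± 1.19 against 4.18 ± 0.27 (log2 difference 4.20) and the integrin gene Itga2b at 8.12 ± 0.29 against 5.06 ± 0.16 (3.05).

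Globin genes were lower in knockout-labelled than in wild-type MDPs, although red blood cells had been lysed and lineage-positive cells sorted out. Erythroid cells in wild-type pool 3 alone are argued against for the globin genes called lower, whose median without that pool was -3.996 (Hbb-b2 -4.49, adjusted p = 2.54e-04; Hba-a1 -3.51, adjusted p = 0.0269), but Hba-a2 was at -0.44 (adjusted p = 0.892), and the test was narrowed to the genes called lower after that value was seen. A candidate explanation is red cell RNA carried into every MDP pool except the knockout-labelled ones: against these, VENUS-positive MDPs had a median of 4.60 for the 3 globin genes (2 called, Hba-a2 standing at 10.93 ± 0.45 against 10.53 ± 0.13) and of 0.285 for the 15 other genes of the list (0 called), 1 of the 18 list genes standing in another list too. Those 15 include megakaryocyte genes. Of their erythroid genes, Slc4a1 differed by 2.58, Car2 by 1.45, Klf1 by 0.99 and Alas2 by 0.33 (limma adjusted p from 0.403 to 0.959). The median of 0.285 therefore does not show that all other erythroid genes were level. Erythroid cells in wild-type pool 3 alone are argued against for Car1 and Car2 too, called lower without it (-2.86 and -2.15, median -2.50, adjusted p = 0.0016 and 0.0395), but for the others they cannot be told apart from a lower level in the knockout-labelled cells, since the median without that pool (-0.685 against -1.28 over all 15, -0.67 against -1.04 over the 13 not called) lies between those that each would give. Cells like VENUS-negative MDPs may also have entered that pool, where 86.9% of 61 genes that were at least 3 log2 units higher in VENUS-negative MDPs were highest among the wild-type pools, but neutrophil, monocyte and NK-cell lists were highest there too, so no single kind of cell stands out.

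Irf8 transcript was not lower in MDPs labelled IRF8 knockout. Whether the pools were wild-type cells was examined with the 37 genes lower in both these and VENUS-negative MDPs, where independent lists give 2.32. Genes higher in both (8 against 2.22) or changed in opposite directions (10 against 2.35 and 9 against 2.19) exceeded independent lists too. An excess over independent lists therefore does not by itself decide the label. With each comparison fitted on its own arrays, 6 genes were lower in both, against 0.371. Both Irf8 probe sets could measure transcript outside the disrupted part of the gene, the lower of their differences being -0.048 (SE 0.22). That cannot be told apart from a label that means something else, because the probe positions and the allele are not given in the sources used here. No biological explanation was tested.

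In VENUS-negative MDPs 9 of 18 erythroid and megakaryocyte genes and 6 of 15 eosinophil, basophil and mast cell genes were called higher and 11 of 33 monocyte and macrophage genes lower (list adjusted p = 0.0913, 0.136 and 0.154 with an estimated correlation). The sex of the pooled mice is argued against as the whole cause, since 14 of 15 marker genes called higher, and 805 of the 1003 called genes, kept their call without VENUS-positive pool 3, the only VENUS pool with a high Xist level. A minor share of other cells among VENUS-positive-like MDPs is argued against for the falls of 11 monocyte genes only. These genes, chosen as called lower, had a median of 6.5% of their VENUS-positive level (for those near background, such as Klf4, only a bound). Csf1r, named before the data were examined, fell 7.62-fold, although the median difference of all 33 genes of that list was -0.27. These falls do not bear on the rises, so whether a minor share of cells gave the rises is left open. Whether most of these cells transcribe no M-CSF receptor gene, although that receptor was part of the gate, is left open: Csf1r lay -3.01 log2 units from its level in receptor-negative granulocytes (SE 0.30, adjusted p = 1.44e-06), but VENUS-positive MDPs (7.89) were also below that level (7.97), so it cannot mark absence of the transcript. A difference between lineages that the reporter separates remains an untested biological explanation.

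The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, the real one included, which are too few for a share under 0.05. The other splits mix both groups, so any difference between the groups enters their spread and lowers their counts of called genes. Those low counts do not show how many genes would be called between groups that are alike. The real and the highest other counts of called genes were 155 and 0 for the knockout comparison, 5337 and 0 for macrophages against granulocytes, 4038 and 0 for macrophages against wild-type MDPs and 7720 and 1 for granulocytes against wild-type MDPs, with 1 split in 10, the real one, reaching the real count in each. For VENUS-positive against wild-type MDPs they were 0 and 2, all 10 splits reaching the real count. The 4 spleen splits that part all 3 pools, the real one included, gave 5337 for the real one and 0 at most for the others. The absolute median of the macrophage signature in the knockout comparison was 0.0691, with 0.148 the highest other and 7 splits as large, and that of the granulocyte signature 0.0064, with 0.194 the highest other and 10 splits as large. For genes lower in both MDP comparisons the counts were 37 and 0, with 1 split as large.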
